A study of Mus musculus with 16 samples.

How the data were processed

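Tail DNA of 8 C57BL/6 mice of 1 family was compared with the DNA of a single reference male mouse from the same colony by array comparative genomic hybridization, in which 2 DNA samples carrying different dyes compete for the same probes. The family consisted of a sire, a dam and 6 progeny. Each animal was hybridized on 2 arrays, once labelled with Cy3 and once with Cy5, so that there were 16 arrays on 4 slides, scanned on 2 days. The sire and the dam shared slide 1, progeny 1 and 2 slide 2, progeny 3 and 4 slide 3, and progeny 5 and 6 slide 4. Slides 1 and 2 were scanned on the first day and slides 3 and 4 on the second. The custom array covered candidate loci of an earlier screen at high density, per the labels, and is not a sample of the whole genome.

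The scanner output held the intensity of every spot in the red (Cy5) and green (Cy3) channels. Per the file headers, the authors extracted these intensities with Feature Extraction 10.7.1.1, which subtracted the background and normalized the dyes, with a linear and a lowess factor listed among its statistics, and placed the probes on mouse genome build mm9. The deposited log10 ratio of red over green from the same software was used to find the direction of the values described next. A deposited table of log2 values for the same spots followed the log ratio of the reference over the animal on every array, with slopes against the log10 ratio of 3.04 to 3.29 on arrays with the animal in Cy3 and of -3.28 to -3.08 on arrays with the animal in Cy5. The column medians of that table lay between -0.002 and 0.011, so that it was centred near 0. It differed from the scanner values probe by probe, and the correction behind this is not given in the sources used here. It served only as an alternative, with its sign turned.

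Each file had 108267 rows, of which 6563 were controls and were left out. The other 101704 spots belonged to 97689 probes, with 97638 on autosomes, 48 on X and 3 on Y. The median step between neighbouring autosomal probes was 88 bp. Between 96 and 152 spots per array carried an outlier flag and were left out. The share of spots well above background was 99.2 to 99.7% per array, and 1098 probes missed this mark on at least 1 array (called dim probes in the following). Median raw green signals were 680 to 890 on the first scan day and 327.5 to 493 on the second, against local backgrounds of 33 to 38. The number of arrays, 2 per animal, limits the precision of each ratio.

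The log2 ratio of processed red over processed green was turned to animal over reference on every array, centred on its median over the autosomal probes, averaged over the spots of a probe and then over the 2 arrays of the animal. No loess or quantile step was applied. Within runs of probes with no gap over 100 kb, a recursive search found the interval with the highest sum of standardized ratios over the square root of the probe number. A segment was called at an interval score over 6 with at least 3 probes, a mean log2 ratio of at least 0.25 in size, and the same sign with at least 0.15 in size on each array. Overlapping calls of the same sign were merged across animals into regions. A region was parental if it was called in at least 1 parent and 1 progeny but not in all 8 animals, parent-only or progeny-only if called on 1 side alone, and uncertain if called in progeny alone with a parent at 0.5 or more of the mean of the carriers. Calls from a single animal have no p-value. False calls were estimated by searching the difference between the 2 arrays of an animal, divided by 2, in which copy number cancels. Artifacts that both arrays share cancel as well, so false calls from these are not counted. The search was done before and after subtraction of the mean of that difference in the other 7 animals. After the subtraction the values were scaled down for the variance it added. They were then searched without the requirement on each array, a looser rule than that of the calls. The subtraction was added after seeing the data, because the uncorrected differences of each animal correlated with the mean of the others at r = 0.74 to 0.84 over the probes.

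Group comparisons used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with Benjamini-Hochberg adjustment at 0.05) on the averaged ratio of each animal, with the groups sire, dam and progeny. The 2 arrays of an animal hold the same DNA and counted as 1 replicate. The residual spread came from the 6 progeny, and the lone sire and dam were assumed to vary like them. Tests against the reference leave out the spread of the reference, which was 1 mouse. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The interval search was tested on simulated independent normal noise with the robust SD of progeny 4 (0.074). It recovered 82% of segments of 3 probes at a log2 of 0.3, 92% of those of 5 probes and 100% of those of 10 probes, with 0 false calls. The real profile of progeny 4 had an SD of 0.14, and outlying probes and dye bias were not simulated. The 0 false calls thus say little about the real profiles, where the control after subtraction gave 14 calls in progeny 4. In data simulated for the progeny against the reference (97544 probes), limma recovered 85 of 100 probes changed by 0.25 and 98 of 100 changed by 0.5, with 9 false calls. For the progeny against the parents it recovered 27 of 100 at 0.25 and 76 of 100 at 0.5, with 6 false calls. Here too the noise was independent and normal, and each change was given to all 6 progeny. The simulated parents were at 0 with the spread of the progeny. Shifts of a parent's own were not simulated, so these figures say little about false calls in the real contrast.

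The rule for naming regions, all thresholds and most alternatives were set before the data were examined. It took up to 10 progeny-only regions by score, the 10 parental and 5 parent-only regions with the highest score, and would have taken 10 regions shared by all 8 animals. The alternatives covered background correction by normexp with an offset of 50 (on median spot signals, where mean signals had been planned), centring by the mode or not at all, the filter on dim or outlier-flagged spots, the deposited log2 table, single dye orientations, each calling threshold, omission of each progeny, slide as a random block and regions in place of probes. A minimum log2 of 0.2, dim probes left out together with a minimum of 10 probes, omission of the sire, and scan day as a block or taken singly were added after seeing the data. The files used name no genes, and the gene table given was for another genome build, GRCm38.p6, so regions are named by mm9 position without gene content. The comparison with gene lists fixed in advance was therefore not run.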

Results

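The series examined whether copy number differences appear in the progeny of male mice kept under continuous gamma irradiation of 1 mGy per day for 400 days. The data were hybridization ratios of tail DNA of 1 sire, 1 dam and their 6 progeny against 1 reference male, on a second, dense array. The series title refers to exposed males, whereas the series text describes the male of this family as non-irradiated, so the exposure of this sire was not settled by the labels. All ratios are log2 of animal over reference, and positions are on mm9.

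X chromosome probes set the scale of a copy number difference. Over 48 X probes the dam had a mean log2 ratio of 0.92 against the male reference, and progeny 3 to 6 had means of 0.88 to 0.95. The sire, progeny 1 and progeny 2 lay between 0.01 and 0.02. Over 3 Y probes the dam was at -2.91 and progeny 3 to 6 at -2.69 to -2.36, while the sire was at -0.12, progeny 1 at -0.03 and progeny 2 at 0.00. The 3 Y probes of the dam ranged from -5.05 to -0.60, and with normexp background correction the dam was at -1.49 and progeny 3 to 6 at -1.17 to -0.96. The labels give no sex for the progeny. The progeny with X and Y levels like those of the dam were those scanned on the second day.

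The 2 dye orientations of an animal correlated weakly or negatively over all autosomal probes. Pearson's r across probes, which are not independent replicates, ranged from -0.27 to 0.07. The dye bias of a probe enters the 2 orientations with opposite sign and lowers r, so r does not measure their common signal alone. Over the probes of called regions with at least 10 probes r was 0.78 to 0.90, but calling itself required the same sign on both arrays. Most of these probes lay in a region on chromosome 4 (1341 probes) and a region on chromosome 14 (1331 probes). Shorter called regions were not covered by this r. The robust SD of the averaged ratio was 0.046 in progeny 2 and 0.074 in progeny 4.

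The search called 145 segments in the 8 animals, with 44 gains and 101 losses. The sire carried 40 of them, 38 being losses, and the dam 13. The progeny carried between 7 calls in progeny 2 and 27 in progeny 6. Most calls were short, and how many calls a control gave beside them depended on length. After removal of the dye bias of each probe, the control in which copy number cancels gave 60 calls at 3 or more probes against 145, 7 at 5 or more probes against 63, and 1 at 10 or more probes against 29. Without that removal the control gave 270, 134 and 17 calls. By animal, the control after removal gave 6 calls in the sire, 5 in the dam, 4 in progeny 1 and 0 in progeny 2. In progeny 3 to 6, scanned on the second day, it gave 8, 14, 6 and 17. The higher count of calls in progeny 6 thus came with the most control calls and does not by itself show more copy number change. The control after removal did not apply the requirement on each array, so its counts come from a looser rule than the calls. An artifact that both arrays of an animal share cancels in the control along with copy number. The control therefore counts only false calls from differences between the 2 arrays, also at 10 or more probes.

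**Figure D1:**
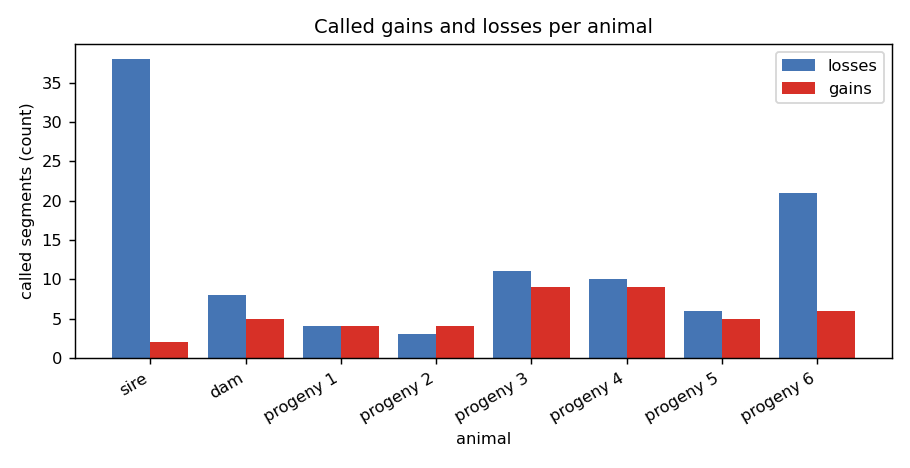
Number of called losses and gains (vertical axis, counts) in the sire, the dam and the 6 progeny (horizontal axis), as bars from 0. The sire had 38 losses and 2 gains, and progeny 6 had 21 losses and 6 gains. The control after removal of dye bias, not drawn, gave 6 calls in the sire and 17 in progeny 6.

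The 145 calls formed 104 regions, where 2 intervals each counted both as a loss in some animals and as a gain in others. Further regions of opposite sign overlapped in part. An example on chromosome 11 was a loss in progeny 4 (76357379 to 76357804) and a gain in progeny 5 (76357469 to 76359537). Of the regions, 12 were parental, 41 parent-only, 28 progeny-only and 23 uncertain. No region was called in all 8 animals. Of the parental regions, 5 were called in the sire and 7 in the dam.

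The region with the most probes was a gain on chromosome 4 (101109089 to 101271085, 1341 probes). The sire had a mean log2 ratio of 0.87 there and the dam 0.00. All 6 progeny carried the gain, at 0.48 ± 0.02 (SD, n = 6), so that each progeny lay between its parents. The 10 probes on either side of the region averaged -0.02 and -0.01 in the sire.

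A deep loss on chromosome 3 (25416456 to 25456050, 147 probes) was called in the dam at -1.92 and in progeny 3 to 6 at -1.89 to -1.85. The sire was at 0.00, progeny 1 at 0.01 and progeny 2 at -0.02. The loss reached the last probe of its tile, so its right end was not covered. A short loss on chromosome 2 (111694136 to 111694677, 6 probes) had the same 5 carriers, with -0.89 in the dam and -1.07 to -0.91 in progeny 3 to 6. The same 5 animals were also higher on chromosome 10 (52260216 to 52264952, 37 probes), with 0.28 in the dam and 0.24 to 0.26 in progeny 3 to 6, although only the dam, progeny 3 and progeny 4 passed the calling limit. The carriers of these 3 regions were the animals with the X and Y levels of the dam.

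A loss on chromosome 3 (125655123 to 125656489, 13 probes, 2 of them dim) was called in the dam and in 3 of the 6 progeny. The dam was at -0.88, progeny 3 at -0.94, and progeny 5 and 6 at -0.92 each. The sire was at 0.06, progeny 1 at 0.00, progeny 2 at 0.03 and progeny 4 at -0.03. In size these carrier means lay close to the mean X ratio of 0.91 (SD 0.02, n = 5) in the dam and progeny 3 to 6.

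**Figure D2:**
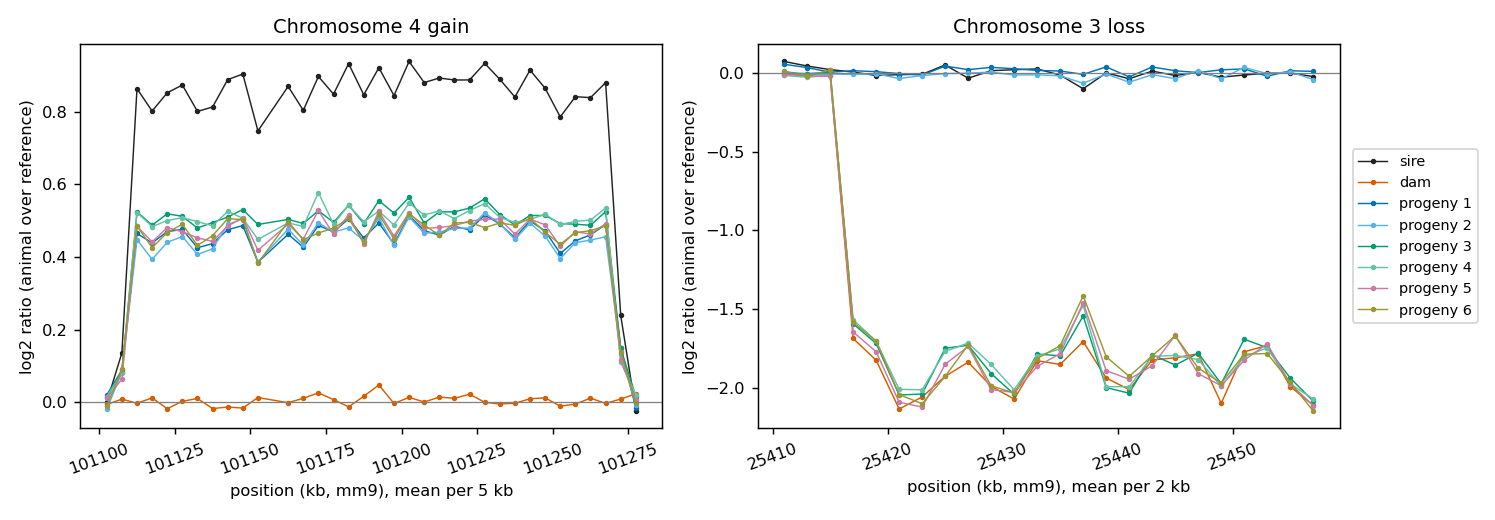
Mean log2 ratio of animal over reference (vertical axes) along chromosome 4 in bins of 5 kb and chromosome 3 in bins of 2 kb (horizontal axes, position in kb on mm9), with 1 line per animal. On chromosome 4 the sire averages 0.87, the progeny 0.48 and the dam 0.00, and on chromosome 3 the dam and progeny 3 to 6 average between -1.92 and -1.85 within the loss.

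A long region on chromosome 14 (53387742 to 54390604, 1331 probes, 77 dim) was lower than the reference in every animal. The means ran from -0.27 in the sire to -0.23 in progeny 5. Only the sire, progeny 1 and progeny 4 passed the limit of 0.25, and with a limit of 0.2, added after seeing the data, the region was called in all 8 animals.

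The other named parental regions had smaller shifts. Those called as losses in the sire lay at chromosome 2 (19839213 to 19840462), chromosome 10 (16581974 to 16583619) and chromosome 11 (110531563 to 110532048). Their sire means were -0.51, -0.41 and -0.43, and the progeny called with the sire had region means of -0.21 to -0.11. All progeny together averaged -0.07, -0.06 and -0.07. The dam was at 0.20, 0.16 and 0.20, and progeny 2 at 0.18, 0.16 and 0.14. The losses called in the sire alone, described below, had medians of 0.16 in the dam and 0.12 in progeny 2. The parental label rests on overlapping calls, and inheritance of the losses at chromosomes 2, 10 and 11 was not tested. A loss on chromosome 5 (69010757 to 69010940) rested on 4 dim probes.

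Of the 41 parent-only regions, 35 were called in the sire and 6 in the dam. The sire had 34 losses of its own, with a median of 5 probes and a median log2 ratio of -0.45, ranging from -0.67 to -0.26. Named examples were chromosome 12 (33939358 to 33940000) at -0.54, chromosome 17 (78328236 to 78328872) at -0.51, chromosome 18 (15829089 to 15829797) at -0.51 and chromosome 4 (106968920 to 106969643) at -0.39. In these 4 regions the dam lay between 0.10 and 0.22. The named dam-only region, on chromosome 2 (100379470 to 100380002), rested on 4 dim probes.

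Among the 28 progeny-only regions, a loss in progeny 1 on chromosome 1 (193318086 to 193324326, 49 probes, none dim) stood apart. Progeny 1 had a mean of -0.69 ± 0.25 (SD over probes), with -0.67 on the array with the animal in Cy5 and -0.72 on the other. The median over the probes was -0.80, and single probes ranged from -0.97 to -0.12. Both parents were at 0.00, and the other 5 progeny lay between -0.01 and 0.02. Its interval score was 94.4. The 10 probes on either side averaged -0.03 and 0.01 in progeny 1.

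**Figure D3:**
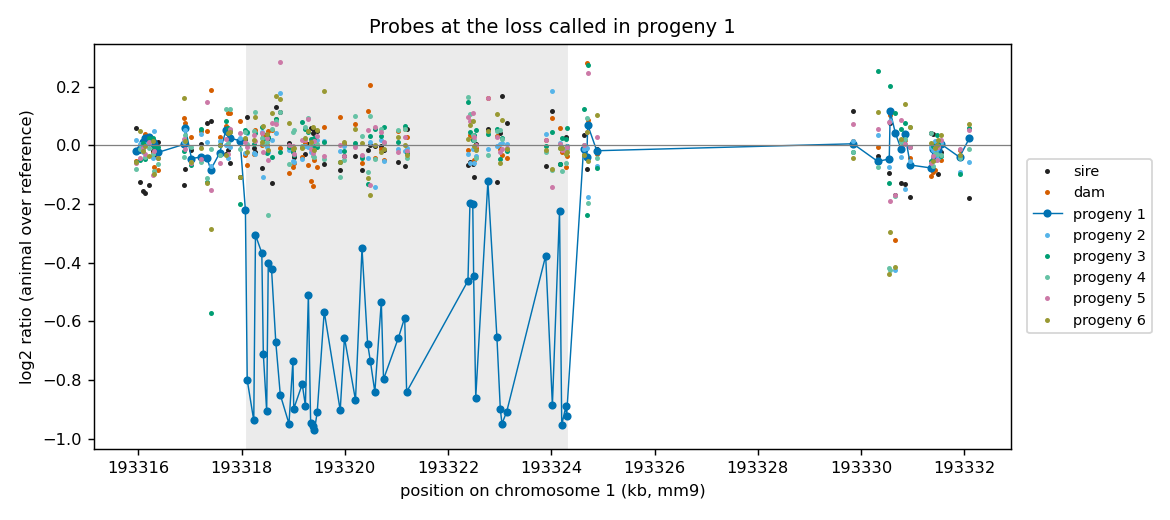
Log2 ratio of animal over reference (vertical axis) of single probes by position on chromosome 1 (horizontal axis, kb on mm9) in 8 animals, with the called region shaded and the probes of progeny 1 joined by a line. Within the shaded region progeny 1 averages -0.69, and the other animals average between -0.01 and 0.02.

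The remaining progeny-only regions were short or dim. Dim probes made up at least 0.5 of the probes in 10 of the 28 regions, including all 9 other regions named. These lay on chromosome 2 (70085845 to 70086354 and 100379270 to 100379529), chromosome 4 (30866826 to 30867992 and 30872319 to 30873464), chromosome 7 (47257059 to 47257308), chromosome 9 (4513667 to 4513978) and chromosome 11 (76357019 to 76357400, 76357379 to 76357804 and 76357469 to 76359537). Of the 18 regions with fewer dim probes, 17 held 3 to 5 probes, with scores of 6.80 to 10.2, and the other was the loss on chromosome 1. When dim probes were left out and at least 10 probes were required, a setting added after seeing the data, 1 progeny-only region was left.

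**Figure D4:**
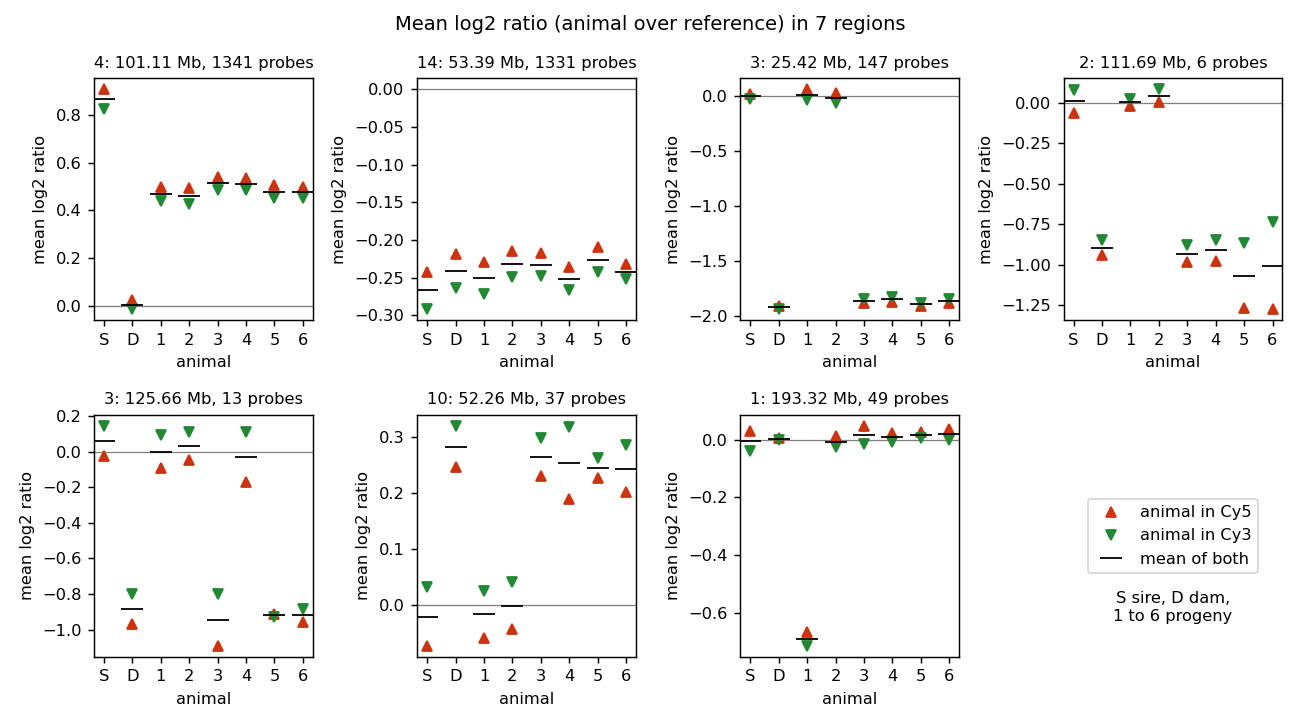
Mean log2 ratio of animal over reference (vertical axes) in 7 regions for the sire (S), the dam (D) and progeny 1 to 6 (horizontal axes), with triangles for the 2 arrays of each animal and a bar for their mean. The vertical scale differs between panels, and the loss on chromosome 1 appears at -0.69 in progeny 1 alone.

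As a group, the progeny differed from the reference at probes that lay mostly in the chromosome 4 and chromosome 14 regions. Of 3335 autosomal probes called by limma among 97638 tested, 1617 were higher and 1718 lower. The chromosome 4 region held 1315 of them and the chromosome 14 region 1038. The 956 called probes outside all called regions had a median change of 0.11 in size. With the 104 regions as the units, limma called 4, with chromosome 4 at 0.48 (SE 0.04, adjusted p = 4.8e-05) and chromosome 14 at -0.24 (SE 0.04, adjusted p = 0.00534). The other 2 were short regions of the uncertain class, named after their values were seen. Chromosome 9 (74330099 to 74330215, 3 probes) was at -0.69 in the progeny (SE 0.12, adjusted p = 0.00926 in limma), with the sire at -0.41 and the dam at -0.44. Chromosome 19 (14671891 to 14672233, 4 probes) was at -0.22 in the progeny (SE 0.04, adjusted p = 0.0212 in limma), with the sire at -0.43 and the dam at -0.07. In each of the 4 regions 6 of 6 progeny had the same sign. The search had called the chromosome 9 region in progeny 2 alone, at -0.50, and the chromosome 19 region in progeny 6 alone, at -0.30. All 4 regions were among the units through calls that included progeny. These tests and the shared sign are therefore not independent of how the regions were selected. The loss on chromosome 3 at 25416456 averaged -1.25 (SE 0.30, adjusted p = 0.061) and was carried by 4 of 6 progeny.

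Few single probes separated the progeny as a group from the mean of the log2 ratios of their parents, and no called region did. In limma, 3 of 97629 probes passed, 2 being higher in the progeny and 1 lower, and 4509 had an unadjusted p under 0.05. These 3 lay on chromosome 2 (70084140 to 70084199), chromosome 10 (101216003 to 101216062) and chromosome 17 (29756643 to 29756699), outside the called regions, and are named after their values were seen. The probe on chromosome 2 was dim (sire -0.90, dam -1.15, progeny -0.02). At the probe on chromosome 10 the progeny, at -0.03, lay near the dam at -0.12, with the sire alone apart at 1.82. At the probe on chromosome 17 the progeny, at -0.78, lay between the sire at -2.86 and the dam at -0.05. Where parents differ widely, a mean of log2 ratios is not the level that 1 chromosome from each would give. These 2 calls thus do not show a change that arose in the progeny. With regions as units 0 of 104 passed in limma, and 1 had an unadjusted p under 0.05. This test takes the mean of all progeny and the spread among them. A change in a lone animal raises that spread and can hardly pass. The loss on chromosome 1 at 193318086, at -0.69 in progeny 1 alone, gave -0.11 (SE 0.19, adjusted p = 0.885 in limma). The test therefore cannot decide whether single progeny differ from their parents. On chromosome 4 the progeny differed from the mid-parent value by 0.05 (SE 0.07, adjusted p = 0.872 in limma).

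The count depended on which progeny were compared with the parents, the 2 scan days holding progeny with different X and Y levels. With scan day as a block limma called 134 probes, 130 of them higher in the progeny, and 123 lay in the chromosome 3 loss at 25416456. On the first scan day alone, with progeny 1 and 2 against both parents, it called 234 probes, 196 of them higher, with 142 in that loss. With progeny 3 to 6 against both parents the direction was opposite, with 115 of 117 called probes lower in the progeny and 107 in that loss. Scan day and X and Y level cannot be separated among the progeny.

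The sire and the dam differed chiefly in the chromosome 4 region. Limma called 1339 of 97629 probes, 1223 higher in the sire and 116 lower, and 1201 of them lay in that region. Its mean was 0.86 higher in the sire (SE 0.12, adjusted p = 0.00882 in limma with regions as units). Another 34 of the 104 regions, covering 32 intervals, were lower in the sire than in the dam in limma. Of these, 28 were losses called in the sire alone. The others were losses called in the sire and in progeny, or overlapped losses called in the sire alone. All were thus picked for a low value in the sire, and the test gives no independent support. The chromosome 3 loss at 25416456 differed by 1.92 between sire and dam but did not pass in limma (SE 1.05, adjusted p = 0.239), the spread being that of the progeny, which differed in carrier state. Per probe, limma called 140 of its 147 probes with scan day as a block, 142 on the first scan day alone and 139 with progeny 3 to 6 alone. Both groups held 1 animal each.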

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

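The tests weighed in this part were chosen after the results were seen. Of 32 measures compared among the 6 progeny, 1 had a lone value far from the others, where chance would give about 1.6, or 1 in 20. It was the loss on chromosome 1 at 193318086 to 193324326, with progeny 1 at -0.69 and a gap to the nearest progeny of 0.964 of the whole range. This region had been called in progeny 1 alone, so its lone value restates how it was selected and is no independent evidence against chance.

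Dim probes do not account for the loss on chromosome 1 in progeny 1, since 0 of its 49 probes were dim, and neither does a fault of a single array, since the smaller mean of the 2 orientations was 0.935 of the larger. A loss in all cells of a parent is excluded for the DNA measured, the lower parent being at -0.00274. A loss of 1 copy in a minority of the cells of progeny 1 would leave the mean above -0.42, and it was -0.69, a level that a loss of both copies in a minority of the cells could also give. A deletion of 1 copy that arose in a parental germ cell or early in progeny 1 may be proposed as a hypothesis, with loss of both copies in a minority of the cells, loss of 1 copy in most but not all cells and parental mosaicism outside the tail left open. An exchange with a sample from outside the family was not tested, although progeny 1 was at 0.47 in the chromosome 4 gain, as its siblings were at 0.46 to 0.51, and at -0.74 at the probe on chromosome 17 at 29756643, where the sire was at -2.86, the dam at -0.05 and its siblings at -0.90 to -0.70.

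The losses on chromosome 3 at 25416456 and chromosome 2 at 111694136 occurred in the dam and progeny 3 to 6. Scan day is argued against by the dam, scanned on the first day and at -1.92. An autosomal deletion passed on by the dam is argued against on chromosome 3, where the progeny carriers had 0.972 of the log2 level of the dam. With 1 chromosome from the sire they would lie at 0.5 of that level or less. On chromosome 2 this ratio was 1.1, which an inherited deletion of 1 copy would also give. Inheritance and linkage to sex therefore cannot be told apart there. Further copies on the X chromosome are argued against by the direction, since these animals had the higher X ratio and yet the highest of their means in the 2 regions was -0.89. Further copies on the Y chromosome would have the direction seen but stay untested, since the match of carriers to the Y level is the pattern itself.

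The 34 short losses called in the sire alone were largely independent of dim probes, with 33 still called without them, and of the scanner software's dye normalization, with 30 still called in ratios of raw signals corrected by normexp. Heterozygous germline deletions are argued against for these losses as a set, since 0 of the 34 reached -0.8 and their median was -0.45. The lowest, at -0.67 over 4 probes, came near the mean of the loss on chromosome 1, with -0.44 and -0.91 on its 2 arrays. The dam lay above 0 in 34 of them, progeny 2 above 0 in 32 and progeny 1 below 0 in 33. A trend along the genome whose strength differs between animals was left open, because in 17436 windows outside all called regions Spearman's rho of the sire was -0.0658 with the dam, 0.48 with progeny 1 and 0.34 with progeny 2, the last going against the signs in the 34 regions. All animals share 1 reference mouse, which by itself can raise these rho values, and no rho without a trend was available to compare. Losses in part of the tail cells of the sire were not tested.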

How the results depend on the processing

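Settings named as added were chosen after the data were seen; the cause of a change was not tested unless stated. Of 25 named regions, 7 were still called in a carrier under all 17 settings of values and thresholds: the gain on chromosome 4, the losses on chromosome 3 at 25416456 and 125655123, that on chromosome 1 at 193318086, and those on chromosome 2 at 19839213, chromosome 10 at 16581974 and chromosome 17 at 78328236. Some settings required at least 5 or 10 probes, which regions with fewer probes could not meet whatever their values. The loss on chromosome 2 at 111694136, with 6 probes, was called in 15 of 17 settings. Absence from this list is therefore partly a matter of length. Presence needed a call in only 1 carrier, so it does not show that progeny were still called. In 65 combinations of region and setting no carrier passed, and 2 progeny-only regions of dim probes turned sign under normexp, chromosome 2 at 100379270 (-0.15) and chromosome 4 at 30872319 (-0.036). The calls fell from 145 to 74 under normexp, to 63 and 29 with at least 5 and 10 probes, and to 64 with a log2 of at least 0.4. They rose to 423 and 372 on the Cy5 and Cy3 orientations alone, where dye bias does not cancel. With dim probes left out and 10 probes required (added) there were 30, and the control without dye bias (added) gave 60. Progeny-only regions went from 28 to 4 under normexp, 18 without dim probes, 79 on Cy5 alone, 7 and 2 with at least 5 and 10 probes, 9 with a log2 of at least 0.4, 44 without the requirement on single arrays and 16 with parents below 0.25 of the carriers. They were 1 with dim probes left out and 10 probes required (added), and 43 without the sire (added), which by construction adds what only the sire had in common with progeny. Leaving out each progeny gave 21 to 27. The chromosome 14 region was called in all 8 animals at a log2 of at least 0.2 (added), and in 4 pieces with tiles broken at 20 kb.

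For the progeny against the reference, the 3335 probes became 42622 and 38882 on Cy5 and Cy3 alone, and leaving out each progeny gave 2747 to 3692. For the progeny against the parents, the 3 probes became 5 with outlier-flagged spots kept, 134 with scan day as a block, 234 on the first scan day alone and 117 with progeny 3 to 6 alone (the last 3 added), and 2 to 4 when each progeny was left out. Regions as units gave 4, 0 and 35 calls for progeny against reference, progeny against parents and sire against dam, there being 104 units. For the sire against the dam, the 1339 probes became 2043 on the first scan day alone (added), where the spread came from 2 progeny, and 1559 with scan day as a block and 1486 with progeny 3 to 6 alone (both added). Slide as a random block left these probe counts at 3164, 3 and 1363. Under normexp the dam was at 0.80 in place of 0.92 on X and at -1.49 in place of -2.91 on Y. No paired analysis was possible because the sire and the dam are single animals and share no numbering with the progeny. The gene lists were not run. Dim probes, with little signal over background, made up at least 0.5 of the probes in 10 of the 28 progeny-only regions.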

Other observations

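All tests in this part were chosen after the results were seen. The gain on chromosome 4 at 101109089 to 101271085 was 0.38 higher in the sire than the mean of the 6 progeny, 17.2 times the SD between progeny. A gain on only 1 of the 2 chromosomes of the sire would give carriers the level of the sire, and would reach 6 of 6 progeny with a chance of 0.0156. A gain on both chromosomes of the sire, passed on as 1 copy to each progeny, may therefore be proposed as a hypothesis.

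The lower ratio on chromosome 14 at 53387742 to 54390604 was nearly equal in all animals, with an SD of 0.0133 between the 8 means. In bins of 100 kb the mean of the 8 animals ranged from -0.37 at 53700001 to 53800000 to -0.06 at 54000001 to 54100000, and the SD between animals stayed under 0.03 in every bin. Over the whole region the means of the 8 animals, at -0.27 to -0.23, lay far from the -0.94 to -0.88 of the carriers of the chromosome 3 loss at 125655123. That argues against loss of 1 copy of the whole region in all cells of the family. Other differences carried by the single reference mouse or by the whole family cannot be told apart, since every array used the same reference. The gene content of the region was not examined and the list of antigen receptor loci, which are rearranged in lymphocytes, was not run, so that somatic rearrangement or the cell makeup of the tail samples also stays open.

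The higher ratio on chromosome 10 at 52260216 to 52264952 was found in the dam and progeny 3 to 6, the animals with the higher X ratio and the lower Y ratio, and no explanation of it was tested.

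A single probe on chromosome 17 at 29756643 to 29756699 was at -2.86 in the sire, -0.05 in the dam and -0.78 ± 0.07 (SD, n = 6) in the progeny, ranging from -0.90 to -0.70. A single probe on chromosome 10 at 101216003 to 101216062 was at 1.82 in the sire, and at -0.08 to 0.01 in the progeny.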
